A study of Mus musculus with 11 samples.

How the data were processed

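The series measured RNA bound to ribosomes by TRAP-seq (translating ribosome affinity purification followed by sequencing) in adult mice of the Glt25d2-EGFP/Rpl10a DU9 line. In this line an EGFP-tagged ribosomal protein is made under the regulatory DNA of Glt25d2, now named Colgalt2, which is active in pyramidal neurons of cortical layer 5. Antibodies against EGFP pull down the tagged ribosomes with the RNA they hold, which is the immunopurified (IP) RNA. Input is RNA before the pull-down and unbound is RNA left after it. Mice took part in a short-access intravenous self-administration study. The 11 libraries are 3 IP libraries each from saline self-administration, cocaine self-administration and yoked controls, 1 input library from the saline group and 1 unbound library from the cocaine group. The labels give cerebral cortex as the tissue, whereas the extraction text names whole striatum. What the yoked animals received, the sex of the animals, and whether replicates are separate animals or pools are not given in the sources used here, so every p-value measures only the spread between libraries.

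The deposited values are raw read counts per gene symbol, with 1 file per library. Per the submitters' processing notes, reads were aligned to mm10 with STAR 2.0.0e and counted with HTSeq, whose version, gene annotation and strand setting are not stated. If counting ignored the strand, antisense and overlapping transcripts add to a gene's count. Reads that align to several places are left out of gene counts, which lowers the values of paralogs and of genes with pseudogene copies, among them ribosomal protein genes. Each file holds 32537 entries, of which 32531 are genes; the special entries for reads given to no gene were left out of library sizes and tests. Reads in genes made up 44.9% to 52.5% of all entries, reads aligned to several places 28.3% to 47.0%, reads outside annotated genes 6.28% to 15.5%, and reads over several genes 1.56% to 7.34%. The ribosomal RNA precursor Rn45s held 3.62% to 8.00% of gene counts and stayed in the library sizes of the comparisons as planned. Library depth ran from 20926712 to 53862653 gene counts. At these depths, counting error is small for genes with many counts, and the spread between libraries sets their precision. Named genes with few counts are an exception, such as Xist at 0 to 40 and Rpl10a at 39 to 151 counts per library. Counts without molecular identifiers also include PCR copies. Positions and gene types come from GENCODE release M21 on GRCm38, the assembly of mm10, which may differ from the annotation the authors counted on; a count is a sum over the gene's exons and does not say which exon or UTR a read came from.

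The 9 IP libraries were fitted together in edgeR 4.0.16 (R 4.3.3) as 3 group means, with TMM scaling, the default expression filter (filterByExpr), robust quasi-likelihood dispersion and Benjamini-Hochberg adjustment over 16417 genes at a threshold of 0.05. Fold changes are given as log2 with the standard error (SE). Contrasts were cocaine against saline, yoked against saline and cocaine against yoked, and a test over both degrees of freedom covered any difference among the 3 groups. Levels as counts scaled to a common library size (CPM) beside a contrast are TMM-scaled over the 9 IP libraries and given as mean ± SD with n = 3 libraries per group; levels and list medians of each single library over the input are scaled over all 11. An exact rank test of 3 against 3 libraries cannot go below p = 0.1, so no such test was used. Sets of genes were tested with camera in limma 3.58.1 on log2 CPM with a preset correlation of 0.01, beside camera with an estimated correlation and beside fry, which asks whether the genes of a set move on balance in 1 direction. Adjustment was over 37 lists per contrast. The lists of cell type markers, RNA quality, response and sample identity genes were fixed before the data were examined; mitochondrially encoded genes matched no gene symbol. Some lists share members, and glial and interneuron markers are found in any cortical tissue.

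The enrichments have 1 input or 1 unbound library, so ratios for each IP library are the main result, and an edgeR test over all 11 libraries, which takes its spread from the groups with replicates, is given beside them. For genes with a mean of at least 1 CPM in the 4 libraries concerned, each IP library was divided by the other fraction after TMM scaling over those 4, with a prior count of 2. A gene was called where all 3 IP libraries differed from the other fraction by at least 2-fold in the same direction. A list's median was placed among 10000 random lists matched on expression. Random genes were drawn independently, so a percentile measures the spread across genes and not between libraries. It is too extreme where the genes of a list vary together. Medians for each replicate number use ratios of CPM with 0.5 added.

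Genes were named by a rule set before the data were examined. Colgalt2 and 8 activity-regulated genes (Fos, Fosb, Arc, Egr1, Npas4, Junb, Nr4a1, Bdnf) were always named. Each contrast names up to 12 genes per direction past the threshold with at least 5 CPM and no overlap between the groups; where fewer than 5 pass, the 5 smallest unadjusted p with the same limits are named and said not to pass. Up to 4 members of each list could be named, and for the enrichments the 12 highest and 12 lowest called genes of at least 10 CPM. Gene models without an established name were counted and not named.

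Alternatives set before the data were examined were RLE and upper-quartile scaling, no filter and a filter of 5 CPM, only the 6 libraries compared, the replicate number as a block, the glial and vascular marker level as a term, only genes above 0 in IP over input, an adjusted p of 0.1, DESeq2 1.42.0, other prior counts (0.5 and 10), and leaving out each library. Runs without the libraries numbered 1, with and without the block, a blocked run without cocaine replicate 1, a run without Rn45s, list tests with a length trend removed, enrichments from parts of the replicates, and simulations of the share of genes without overlap and of the alternatives to the correlation of changes were chosen after seeing the data. For the length trend, a smooth curve on log2 transcript length was removed from each library's deviation from the gene means, over the 15041 genes with a known length; values before removal are on the same genes. Lane and treatment cannot be told apart, because each treatment's IP libraries ran on a lane of their own; the labels give each replicate number its own index sequence in all 3 groups, so number and index cannot be told apart either. As a check on pairing, libraries of the same number correlated at 0.376 to 0.794 after group means were removed, and 6 of the 9 correlated best with a library of their own number. The range was 0.756 to 0.794 for number 1, 0.552 to 0.623 for number 2 and 0.376 to 0.479 for number 3. Between groups, number 2 with number 3 gave 0.370 to 0.621, so only the libraries numbered 1 stood apart. The unblocked fit stayed the main one because it was fixed beforehand, and blocked values are given beside it. The procedure was tested on simulated data made from these libraries. At a true 2-fold change, 11.0% of the changed genes were recovered without the block and 99.0% with it; at a 4-fold change, the shares were 76.0% and 100.0%. Both folds were in the same simulated counts, in which the blocked fit also called 8 unchanged genes and the fit without the block 0. The changed genes were drawn only from genes with many counts, so the recovered shares do not cover weakly expressed genes. The simulation gave every group the same replicate-number means and drew counts with the dispersion of the blocked fit. The gain from the block was thus built in. These shares do not show how often such changes would be found in the real libraries. Camera found an immediate early list shifted by 1.5-fold (adjusted p = 1.3e-23) and called 0 of the 36 other lists. Because the simulated genes varied independently, this does not show how the preset correlation performs where genes of a list vary together. With an estimated correlation the shifted list was missed without the block (adjusted p = 0.0703) and found with it (0.0113). Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 read the counts and drew the figures. Read-level processing was not repeated, and splicing and allele use were not analysed here.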

Results

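RNA was measured in 9 immunopurified (IP) libraries, 3 each from mice that self-administered saline, mice that self-administered cocaine and yoked controls, with 1 input library from the saline group and 1 unbound library from the cocaine group. Total gene counts were 53862653, 37812193 and 38846452 for saline IP replicates 1, 2 and 3, 42613969, 33633470 and 36582541 for cocaine, and 38343099, 37896218 and 33664271 for yoked. The input held 39901884 and the unbound library 20926712. Between 18695 and 20383 genes had at least 1 count in a library. The Y-linked RNA helicase Ddx3y stood at 55.3 to 80.7 CPM in all 11 libraries and Xist, transcribed from the inactive X chromosome, at most at 1.06 CPM.

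The gene whose regulatory DNA drives the tag, Colgalt2, encodes a collagen galactosyltransferase and lies on the plus strand of chromosome 1 from 152399830 to 152510695 (mm10). Its level was highest in replicate 1 of each group, at 138.2 CPM in saline, 139.9 in cocaine and 152.0 in yoked, against 81.4 CPM in the input and 70.3 in the unbound library. In the 6 libraries numbered 2 or 3 it lay between 76.3 and 105.1 CPM. Fezf2, a transcription factor that specifies layer 5 projection neurons, stood at 131.5 to 157.0 CPM in the libraries numbered 1, at 54.5 to 82.9 CPM in those numbered 2 or 3, and at 61.4 CPM in the input. The astrocyte glutamate transporter Slc1a3 was at 27.1 to 50.6 CPM in the libraries numbered 1, at 65.3 to 107.5 CPM in the other 6, and at 89.5 CPM in the input. Malat1, a noncoding RNA kept in the nucleus (chromosome 19, 5795690 to 5802672), was at 101.5 to 237 CPM in the libraries numbered 1, at 1544 to 5399 CPM in the other 6, at 3963 CPM in the input and at 11967 CPM in the unbound library.

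**Figure D1:**
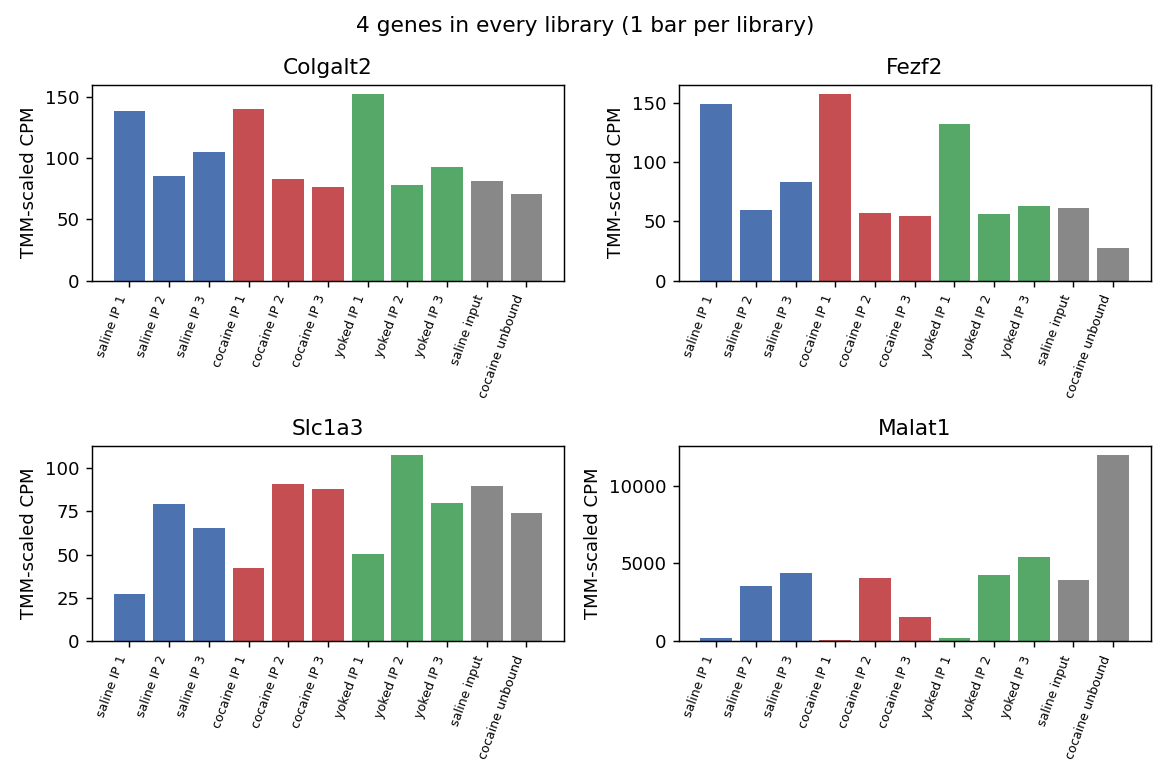
TMM-scaled CPM of Colgalt2, Fezf2, Slc1a3 and Malat1 in each of the 11 libraries (y axis, linear from 0; 1 bar per library on the x axis, so no error bars; blue saline, red cocaine, green yoked, grey input and unbound). In each treatment group replicate 1 has the highest Colgalt2 and Fezf2 and the lowest Slc1a3 and Malat1.

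Saline IP over saline input asks which cell types the immunopurified RNA represents. The input ran on another lane than the saline IP libraries, so fraction and lane cannot be told apart. Layer 5 pyramidal tract neuron markers were at a median log2 ratio of 1.07 in saline replicate 1, −0.02 in replicate 2 and 0.36 in replicate 3, and the median of their mean ratios was 0.44, above all 10000 random lists. Among them Bcl11b, a transcription factor of these neurons, had a mean log2 ratio of 0.66 ± 0.36 (SD, n = 3), and Colgalt2 of 0.40 ± 0.34 (SD, n = 3). Markers of other cells lay below the input on average, with medians of the mean ratio of −0.53 for astrocytes, −0.53 for oligodendrocytes, −0.72 for oligodendrocyte precursors, −0.78 for microglia, −0.34 for inhibitory interneurons, −0.27 for layer 6, −0.21 for layers 2 to 4 and −0.20 for striatal projection neurons. The depletion was largest in replicate 1, in which the astrocyte median was −1.25 against −0.10 and −0.34 in replicates 2 and 3. Replicate 3 showed it too, with astrocyte and oligodendrocyte markers (−0.26) below all 10000 random lists, and oligodendrocyte precursors (−0.38), microglia (−0.41) and layers 2 to 4 (−0.13) at percentiles of 0.09, 0.45 and 0.04. In replicate 2 the 4 glial lists lay at percentiles of 6.81 to 10.9. The myelin gene Mobp, for example, had a mean log2 ratio of −0.95 ± 1.34 (SD, n = 3). Endothelial and mural cell markers were above the input in all 3 libraries, with medians of 0.95, 0.58 and 0.28. Immediate early genes were below it in all 3, with medians of −0.23, −0.13 and −0.35.

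Of 13478 genes, 10 were at least 2-fold higher and 6 at least 2-fold lower than the input in all 3 saline libraries, and the naming rule named none of them. The only 1 of the 16 with 10 CPM or more was AK140265, a transcript model chosen after its values were seen, at 1651 CPM in the input and 155.7 to 370.1 CPM in saline IP. Counted library by library, 371 genes were at least 2-fold higher and 1520 lower in replicate 1, 62 and 35 in replicate 2, and 69 and 85 in replicate 3. The joint counts became 16 and 10 without replicate 1, 27 and 41 without replicate 2, and 26 and 12 without replicate 3, since fewer libraries then have to pass. An edgeR test over all 11 libraries, which assumes that the lone input varies like the other groups, called 0 genes.

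Cocaine IP over cocaine unbound compares the pulled-down RNA with what stayed behind. The unbound library ran on another lane than the cocaine IP libraries and its library number is far from theirs, so fraction cannot be told apart from lane or preparation. Layer 5 markers were above the unbound fraction in all 3 libraries, with median log2 ratios of 1.53, 0.74 and 0.56, but Bcl11b lay below it in all 3 (−0.80 ± 0.09, SD, n = 3). Over the saline input, the layer 5 medians of the same libraries were 0.86, 0.02 and −0.10. In replicates 2 and 3 the rise was thus seen only against the unbound library. The 4 hippocampal neuron markers had medians of 1.53, 0.62 and 0.37. However, Tdo2 and Spink8 were at 0.99 CPM and Fibcd1 at 1.49 CPM in the unbound library. Prox1, at 23.9 CPM there, had log2 ratios of −1.60, −0.07 and 0.10. These 4 genes cannot tell whether the rise was particular to layer 5. Oligodendrocyte markers were below it in all 3 (−1.34, −0.49 and −0.40), as were interneuron markers (−1.15, −0.58 and −0.27) and nuclear noncoding RNAs (−4.0, −0.70 and −1.14). Astrocyte markers were below it in replicate 1 (−0.95) and above it in replicates 2 (0.20) and 3 (0.17). Proteasome subunits were above it in all 3, with medians of 1.32, 0.40 and 0.56.

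Of 13527 genes, 54 were at least 2-fold higher in all 3 cocaine IP libraries than in the unbound library and 299 at least 2-fold lower. Among genes with an established name and at least 10 CPM in either fraction, the highest was Kalrn, a guanine nucleotide exchange factor of dendritic spines (chromosome 16, 33969073 to 34573532), at 3.38 ± 0.31 on the log2 scale (SD, n = 3; 4827 ± 975 CPM against 457.3 in unbound). Next came the autophagy gene Atg7 (2.85 ± 1.02) and Lrguk (2.50 ± 0.22), followed by Sh2d3c, Chst8, Aimp2, Ubb, Rrp12, Haghl, Asb6, Mgst3 and Bnip1, at 2.08 to 1.48. The lowest such gene was Ttr, the choroid plexus transport protein for thyroid hormone (chromosome 18, 20665280 to 20674321), at −5.41 ± 1.24, though gene models without an established name lay lower still, among them AK140265 at −8.63 ± 0.81. Malat1 (−3.86 ± 2.76), Snhg11 (−3.67 ± 0.68), Cdr1, Tmem181b-ps, Firre, Meg3, Trank1, Wsb1, Snhg14, Igf2 and Vcan followed, the last at −2.36; Firre, Meg3 and Snhg14 are noncoding RNAs like Malat1. The saline input was also at least 2-fold above the same unbound library for 50 of the 54 higher genes and at least 2-fold below it for 280 of the 299 lower ones. Leaving out replicate 1, 2 or 3 gave 168, 239 or 123 higher and 459, 396 or 305 lower genes, and edgeR over all 11 libraries called 3 higher and 17 lower.

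Replicate number separated the 9 IP libraries more than treatment did. On principal components of all 11 libraries, the first held 58.2% of the variance and put the 3 libraries numbered 1 at 67.0 to 108.7 and all others at −8.21 or lower. Within each number, cocaine stood highest on it, then saline, then yoked. The values in this order were 108.7, 82.3 and 67.0 in number 1 and −34.7, −37.2 and −40.3 in number 2. In number 3 they were −8.21, −29.8 and −48.9. With the number as a term, 7827 of 16417 genes (47.7%) passed the edgeR test for it. Libraries numbered 1 were higher than the mean of numbers 2 and 3 in 4533 genes and lower in 4550, with 508 at least 2-fold higher and 2286 at least 2-fold lower, whereas number 3 over number 2 passed in 0 genes. In libraries numbered 1, 12 of 14 layer 5 markers rose and 0 fell (median log2 0.93). Of the cell types not targeted, 10 of 12 oligodendrocyte markers fell (median −0.89), as did 8 of 12 astrocyte (−1.02), 7 of 8 oligodendrocyte precursor (−1.32), 6 of 12 microglia (−1.04), 13 of 16 interneuron (−0.67), 8 of 10 layer 6 (−0.50), 7 of 10 layer 2 to 4 (−0.77), 9 of 16 striatal (−0.38) and 4 of 8 thalamic markers (−0.39). Not every other cell type fell. Of the rest, 7 of 12 endothelial and mural markers rose and 3 fell (0.59), and 2 of 4 hippocampal markers rose and 1 fell (0.49). Nuclear noncoding RNAs fell in 7 of 8 (−3.94). Oxidative phosphorylation genes rose in 73 of 80 (1.0), ribosomal protein genes in 66 of 78 (0.79), proteasome subunits in 34 of 38 (0.69) and endoplasmic reticulum stress genes in 15 of 17 (0.64). As sets, none of these lists passed with an estimated correlation (adjusted p = 0.499 to 0.943). Over the input, the layer 5 median was 1.08, 0.86 and 0.90 in the libraries numbered 1 of saline, cocaine and yoked, and −0.10 to 0.38 in the other 6. Reads outside annotated genes made up 6.28% to 7.29% in the libraries numbered 1 and 10.3% to 15.5% in the others.

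**Figure D2:**
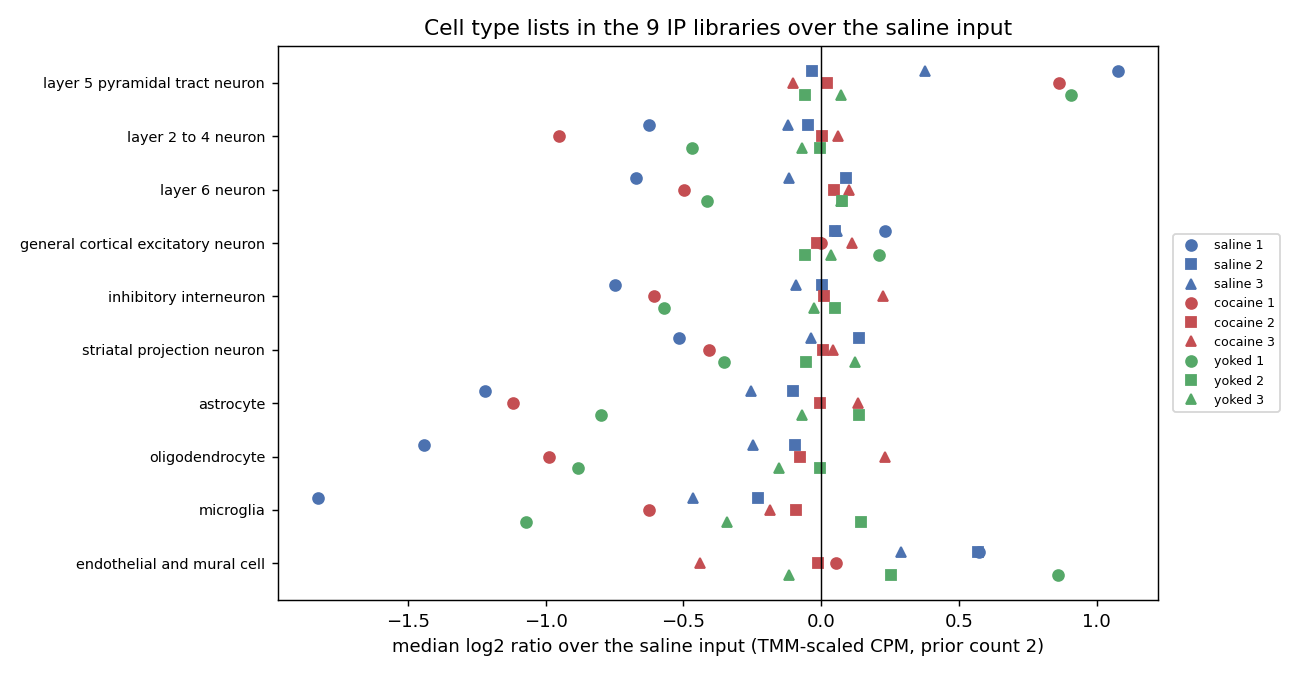
Median log2 ratio of each cell type list over the saline input (x axis, TMM-scaled CPM with a prior count of 2) in the 9 IP libraries, 1 point per library (blue saline, red cocaine, green yoked; circle, square and triangle for replicates 1, 2 and 3). For layer 5 markers the circles lie at 0.86 to 1.08 and the other 6 libraries at −0.10 to 0.38.

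Cocaine against saline compares the IP libraries of the saline and cocaine self-administration groups. In IP libraries numbered 2 or 3, layer 5 medians over the input were −0.10 to 0.38. Malat1 was at 1544 to 5399 CPM in them, against 3963 CPM in the input. These libraries are thus not shown to hold mainly ribosome-bound RNA. The contrasts cannot be read as changes in ribosome-bound RNA of layer 5 neurons alone. No single gene passed the test. Sets of genes were called with the preset correlation, but 0 sets with an estimated correlation (lowest adjusted p = 0.265) or with fry (0.447). The blocked fit gave 0 as well by both (0.340 and 0.254), and so did removal of a length trend, with or without the block. Glutamate receptor genes were lower after cocaine as a set, with 18 of 22 members below saline and a median log2 fold change of −0.18 (camera adjusted p = 0.000549; adjusted p = 0.265 with an estimated correlation). Among them were the AMPA receptor subunits Gria1 (−0.24 ± 0.15 SE; 161.9 ± 11.9 CPM against 191.1 ± 6.50, SD, n = 3 each) and Gria3 (−0.23 ± 0.16), and the NMDA receptor subunit Grin2b (−0.53 ± 0.32). The set was called whichever of the 9 libraries was left out, the only 1 of the 16 called lists of which this was true. Its medians within replicate numbers 1, 2 and 3 were −0.28, −0.08 and −0.18. The call ended when a trend with transcript length was removed from each library (adjusted p = 0.000312 before and 0.130 after on the same genes; 0.0628 after with the replicate block). The median difference in log2 CPM then shrank from −0.18 (SD 0.17 across the 22 genes) to −0.08 (SD 0.14).

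Other gene sets of neuronal signalling were also called lower. Voltage-gated sodium and calcium channels had 26 of 33 members below saline (median −0.13, adjusted p = 0.00118, and adjusted p = 0.265 with an estimated correlation), among them the sodium channel Scn8a at −0.29 ± 0.17. Potassium channels had 27 of 36 below (−0.13, 0.00211, and adjusted p = 0.576 with an estimated correlation). Synaptic scaffold and adhesion genes had 25 of 29 below (−0.13, 0.000221, and adjusted p = 0.265 with an estimated correlation), among them Dlgap1 at −0.32 ± 0.18. GABA receptors had 12 of 14 below (−0.15, 0.00309, and adjusted p = 0.579 with an estimated correlation). Neuropeptides were called higher, with 16 of 17 above saline (median 0.37, adjusted p = 0.000800, and adjusted p = 0.265 with an estimated correlation); Cartpt, the cocaine- and amphetamine-regulated transcript, was at 0.64 ± 0.22 (4.85 ± 0.606 against 3.11 ± 0.0998 CPM, SD, n = 3 each). Without cocaine replicate 1 the calls ended for potassium channels (adjusted p = 0.593), scaffold genes (0.0560), sodium and calcium channels (0.0555) and neuropeptides (0.159). Without saline replicate 1 they ended for sodium and calcium channels (0.0600) and GABA receptors (0.791), the last also without cocaine replicate 3 (0.159) and without all libraries numbered 1 (0.115). Removal of the length trend ended all 5 of these calls. Potassium channels were then at 0.122 (median −0.17, SD across genes 0.29, before and −0.07, SD 0.28, after). The others were sodium and calcium channels (0.302; −0.16, SD 0.17, and −0.05, SD 0.13), scaffold genes (0.276; −0.14, SD 0.17, and −0.02, SD 0.13), GABA receptors (0.217; −0.13, SD 0.15, and −0.06, SD 0.13) and neuropeptides (0.0851; 0.28, SD 0.24, and 0.10, SD 0.20). Of these 5, only neuropeptides were called with the replicate block as well (0.0213).

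Markers of the targeted and of other cells moved as well. Layer 5 markers were called lower, with 13 of 14 below saline and a median of −0.24 (adjusted p = 0.00118; adjusted p = 0.579 with an estimated correlation), among them Bcl11b at −0.54 ± 0.24 (150.5 ± 8.47 against 218.3 ± 57.9 CPM, SD, n = 3 each). Microglia markers were called higher as a set, with 11 of 12 above saline (0.49, 0.000623, and adjusted p = 0.579 with an estimated correlation), with the receptor Csf1r at 0.45 ± 0.29. So were the sets of astrocyte markers, with 11 of 12 above (0.26, 0.0106, and adjusted p = 0.579 with an estimated correlation), and oligodendrocyte markers, with 12 of 12 above (0.28, 0.0190, and adjusted p = 0.650 with an estimated correlation), with the myelin enzyme gene Cnp at 0.40 ± 0.22. Endothelial and mural markers were called lower as a set, with 11 of 12 below saline (−0.39, 0.00118, and adjusted p = 0.265 with an estimated correlation), among them Flt1 at −0.65 ± 0.38. Without saline replicate 1, in which layer 5 markers stood highest over the input, the calls ended for layer 5 (0.831), microglia (0.454) and astrocyte markers (0.831), and for oligodendrocyte markers with the direction turned (0.779). Without cocaine replicate 2 they ended for layer 5 (0.0935), astrocyte (0.205) and oligodendrocyte markers (0.294), and without cocaine replicate 3 for these 3 (0.214, 0.390 and 0.679) and for endothelial markers (0.0515). These runs leave the replicate numbers unequal between the groups. Where the numbers stayed equal all 5 were called, with the replicate block (layer 5 0.000109, microglia 0.00107, astrocyte 0.00132, oligodendrocyte 0.000220, endothelial 0.000506) and without all libraries numbered 1 (1.4e-05, 0.0268, 0.000117, 0.000201 and 0.000117). Equal numbers do not make purification equal. Layer 5 medians over the input were 1.08, −0.03 and 0.38 in saline replicates 1, 2 and 3. In cocaine they were 0.86, 0.02 and −0.10. These calls cannot be told apart from a difference in purification between the groups. With the length trend removed, layer 5 (0.0261), microglia (0.00443), astrocyte (0.0172) and endothelial markers (0.00292) were called and oligodendrocyte markers were not (0.0512; median 0.31, SD across genes 0.16, before and 0.26, SD 0.15, after). All 5 were called with the block and the trend removed together (layer 5 6.7e-06, microglia 0.00579, astrocyte 0.000762, oligodendrocyte 0.000439, endothelial 0.000119), but 0 of them with an estimated correlation (0.443 to 0.457) or with fry (0.322 to 0.416).

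Genes of energy and protein turnover were called higher after cocaine, by most within replicate number 1. The same lists were higher in the libraries numbered 1 than in the others. Cocaine also stood nearest to that side of the first principal component within each number. A cocaine effect on these lists cannot be told apart from that component, in this contrast or against yoked. Oxidative phosphorylation genes were above saline in 80 of 80 (median 0.39, adjusted p = 2.4e-05, and adjusted p = 0.682 with an estimated correlation), ribosomal protein genes in 73 of 78 (0.39, 4.7e-06, and adjusted p = 0.650 with an estimated correlation), and proteasome subunits in 36 of 38 (0.32, 4.7e-06, and adjusted p = 0.650 with an estimated correlation). Within numbers 1, 2 and 3 the oxidative phosphorylation median was 0.72, 0.13 and −0.05, and the ribosomal protein median 0.76, 0.11 and −0.02. Without cocaine replicate 1 both were called in the opposite direction (adjusted p = 6.3e-06 and 0.0019), and the proteasome call ended with its direction turned (0.658). That run keeps saline replicate 1, in which oxidative phosphorylation genes stood 0.73 above the input. All 3 were called higher with the replicate block (3.8e-12, 4.6e-09 and 4.3e-12). They were also called with the length trend removed (0.0261, 0.0113 and 0.00292), though their median differences in log2 CPM shrank. The oxidative phosphorylation median went from 0.28 (SD across genes 0.16) to 0.11 (SD 0.17), the ribosomal protein median from 0.29 (SD 0.18) to 0.13 (SD 0.19) and the proteasome median from 0.29 (SD 0.15) to 0.17 (SD 0.14). The complex I gene Ndufb8, at 0.75 ± 0.48, stood at −0.13 without cocaine replicate 1. Cox6a2, a cytochrome oxidase subunit, was at 0.83 ± 0.30, Rps10 at 0.85 ± 0.46 and the proteasome gene Psmd13 at 0.51 ± 0.32. Without all libraries numbered 1, the proteasome call held (3.3e-09) and those of oxidative phosphorylation (0.103) and ribosomal protein genes (0.241) did not. The oxidative phosphorylation call also ended without saline replicate 2 (0.154). Histone genes were called higher as a set, with 25 of 25 above saline (0.41, 0.0190, and adjusted p = 0.650 with an estimated correlation), which ended without cocaine replicate 1 with the direction turned (0.356), saline replicate 2 (0.186), saline replicate 3 (0.163) or all libraries numbered 1 (0.429), or with the length trend removed (0.302; median 0.30, SD across genes 0.23, before and 0.15, SD 0.24, after). Nuclear noncoding RNAs, a list for RNA quality, were below saline in 7 of 8, without a call (−0.27, 0.367; 0.000218 with the replicate block and 0.000117 without the libraries numbered 1; adjusted p = 0.810 with an estimated correlation). Their medians within numbers 1, 2 and 3 were −0.45, 0.03 and −0.59. With the length trend removed they were called with the block (0.0253) and not without it (0.760), at a median of −0.43 (SD 0.44) before and −0.15 (SD 0.36) after. Cholesterol synthesis genes were called higher as a set, with 14 of 19 above saline (0.18, 0.00720, and adjusted p = 0.579 with an estimated correlation), which ended without cocaine replicate 1 (0.351), cocaine replicate 3 (0.0640), saline replicate 2 (0.189) or saline replicate 3 (0.0600).

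Immediate early genes, which neurons switch on after activity, were above saline in 24 of 30 (median 0.11), short of a call (adjusted p = 0.0557; 0.00544 with the replicate block and 8.2e-05 without the libraries numbered 1; adjusted p = 0.650 with an estimated correlation). The nuclear receptor Nr4a1 (chromosome 15, 101254269 to 101274795) was at 0.39 ± 0.24 (58.2 ± 4.23 against 44.3 ± 9.59 CPM, SD, n = 3 each), Arc (chromosome 15, 74669083 to 74672570) at 0.43 ± 0.34, Fos at 0.36 ± 0.47 and Junb at 0.31 ± 0.36. With the replicate block, 5 of the 30 passed when adjusted over the list alone and 0 over all genes: Ier5 (0.50 ± 0.12), Egr2 (0.93 ± 0.25), Arc (0.45 ± 0.13), Nr4a1 (0.42 ± 0.13) and Ier2 (0.70 ± 0.23). In the same blocked fit 3 of 14 layer 5 markers passed when adjusted over the list alone and 0 over all genes, namely Npr3 (−0.48 ± 0.13), Pou3f1 (−0.42 ± 0.12) and Bcl11b (−0.49 ± 0.15). Markers of cells not targeted did so too, with 3 of 12 astrocyte and 3 of 16 interneuron markers higher and 4 of 12 endothelial and mural markers lower. Ier5, Egr2, Ier2 and Pou3f1 were chosen after their values were seen; unblocked, Pou3f1 turned to 0.04 without saline replicate 1. The other named genes of this kind lay near 0, with Fosb at 0.12 ± 0.28, Egr1 at 0.11 ± 0.29, Bdnf at 0.10 ± 0.24 and Npas4 at −0.07 ± 0.39, and Colgalt2 at −0.12 ± 0.33. Leaving out 1 library turned the sign of these 5: Fosb to −0.18 and Egr1 to −0.10 without cocaine replicate 2, Egr1 to −0.03 without saline replicate 3, Bdnf to −0.07 and Npas4 to 0.02 without cocaine replicate 1, Bdnf to −0.05 and Npas4 to 0.25 without saline replicate 2, Npas4 to 0.16 and Colgalt2 to 0.02 without cocaine replicate 3, and Colgalt2 to 0.09 without saline replicate 1.

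Gene by gene, edgeR called 0 genes between cocaine and saline (lowest adjusted p = 0.9998), with 168 at an unadjusted p under 0.05, 105 higher and 63 lower. DESeq2 called 0 and had 289, and the blocked edgeR fit called 0 (lowest adjusted p = 0.377) and had 2023. The groups did not overlap in 5.39% of genes. Chance gives 10% for independent libraries, and 3.16% to 3.64% in 20 simulations without effects that kept the replicate-number differences. These simulations drew each gene independently of the others, so their ranges are too narrow where genes vary together. In the unblocked edgeR fit 0 members of each list passed over all genes and 0 adjusted over the list alone; with the block some passed over the list alone, as many as 5 of 17 neuropeptides. The smallest unadjusted p among higher genes, none of which pass, belonged to Jam3, an adhesion molecule gene (chromosome 9, 27097384 to 27155421), at 0.60 ± 0.18 (9.74 ± 0.362 against 6.43 ± 0.455 CPM, SD, n = 3 each), the proline catabolism gene Aldh4a1 (0.72 ± 0.22), the ciliary transport gene Ift27 (0.51 ± 0.16), Nmral1 (0.75 ± 0.25) and Aldoc, a glycolytic enzyme of astrocytes (chromosome 11, 78322968 to 78327781), at 0.51 ± 0.17 (444.7 ± 44.8 against 311.3 ± 33.9 CPM, SD, n = 3 each). Among lower genes they belonged to the kinase anchoring gene Akap12 (chromosome 10, 4266380 to 4359470) at −0.67 ± 0.17 (12.6 ± 2.25 against 20.1 ± 1.01 CPM, SD, n = 3 each), the secreted signal Wnt5a (−0.76 ± 0.23), Qtrtd1, which modifies transfer RNA (−1.23 ± 0.38), the natriuretic peptide receptor Npr3 (chromosome 15, 11839896 to 11907287) at −0.47 ± 0.16 and the ubiquitin ligase Ube3a (−0.48 ± 0.17). The lists for layers 2 to 4, general cortical excitatory, thalamic and hippocampal neurons, none of them called, had a median, a mean and a test that differed in sign.

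**Figure D3:**
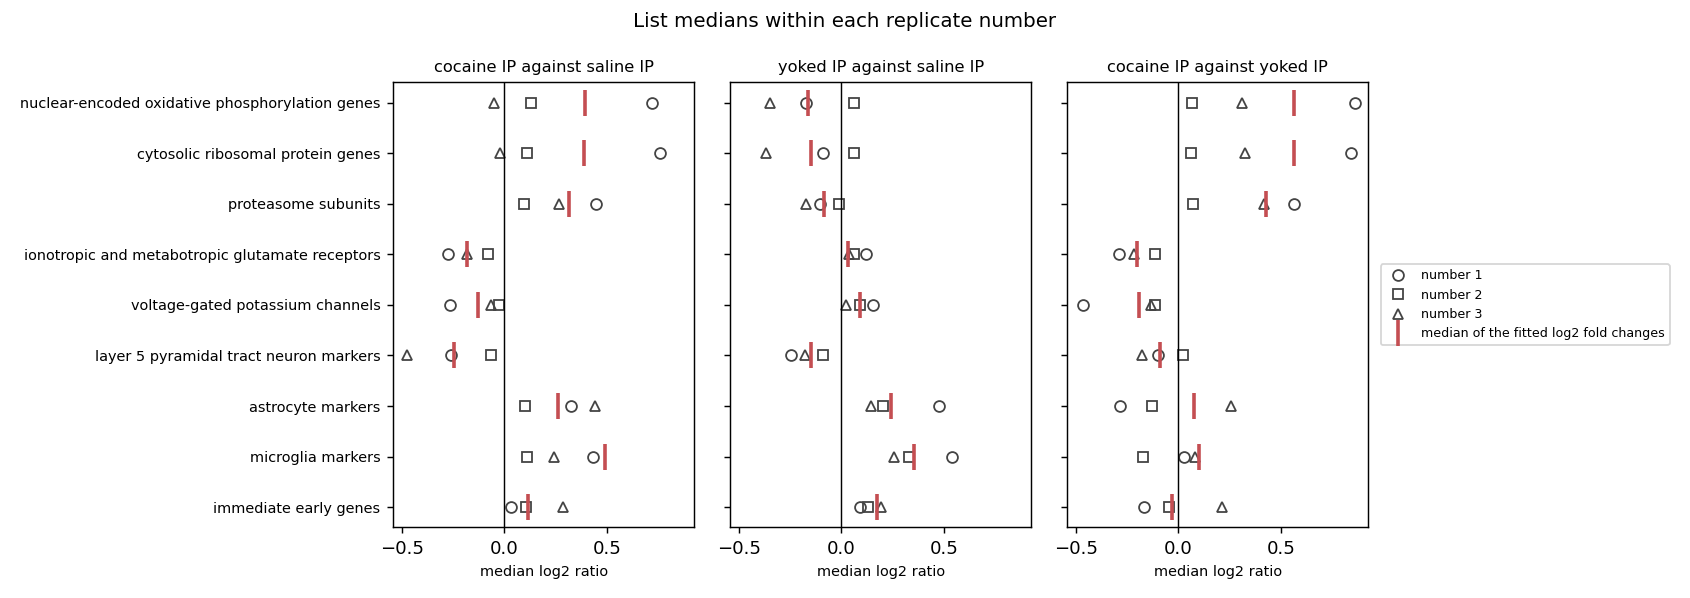
Median log2 ratio of 9 gene lists (x axis) in each of the 3 comparisons, with 1 point per replicate number (circle 1, square 2, triangle 3) and a red bar at the median of the fitted log2 fold changes. Glutamate receptor genes lie below 0 in all 3 numbers for cocaine against saline (−0.28, −0.08, −0.18) and cocaine against yoked (−0.29, −0.12, −0.22), while oxidative phosphorylation genes are farthest out in number 1 (0.72 and 0.86).

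Yoked against saline compares the yoked controls with saline self-administration. Microglia and astrocyte markers and immediate early genes were called higher as sets, and oxidative phosphorylation, ribosomal protein and proteasome genes lower, but not 1 of the 9 called lists was called whichever library was left out. For all 9, the adjusted p = 0.956 with an estimated correlation. With the replicate block 0 lists were called with an estimated correlation (lowest adjusted p = 0.747) or with fry (0.485). Microglia markers were above saline in 11 of 12 (median 0.36, adjusted p = 0.000150), with Csf1r at 0.73 ± 0.29 (5.41 ± 1.08 against 3.27 ± 1.20 CPM, SD, n = 3 each). Astrocyte markers were above it in 11 of 12 (0.24, 0.0102), with Slc1a3 at 0.47 ± 0.45 and Aldoc at 0.25 ± 0.17. Both calls ended without saline replicate 1 (0.455 and 0.882) or yoked replicate 2 (0.0629 and 0.456). Both held with the replicate block (7.2e-06 and 2.6e-06), without all libraries numbered 1 (0.00991 and 0.00869) and with the length trend removed (2.0e-05 and 0.00584). Layer 5 medians over the input were 1.08, −0.03 and 0.38 in saline replicates 1, 2 and 3, and 0.90, −0.06 and 0.07 in yoked. Here too a difference in purification cannot be told apart from one of treatment. Haemoglobins were above saline in 3 of 3 (0.54, 0.0302), cholesterol synthesis genes in 17 of 19 (0.10, 0.0102) and sodium and calcium channels in 24 of 33 (0.08, 0.0471). Layer 5 markers were below saline in 14 of 14 (−0.15), short of a call (0.0558; 0.000229 with the replicate block), with Bcl11b at −0.38 ± 0.24.

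Immediate early genes were above saline in 21 of 30 after yoking (median 0.17, adjusted p = 0.0302, and adjusted p = 0.956 with an estimated correlation). Nr4a1 was at 0.58 ± 0.24 (66.1 ± 18.5 against 44.3 ± 9.59 CPM, SD, n = 3 each), Arc at 0.58 ± 0.34, Fos at 0.40 ± 0.47 and Fosb at 0.24 ± 0.28, whereas Npas4 was at −0.41 ± 0.39. With the replicate block, Nr4a1 (0.57 ± 0.13) and Arc (0.54 ± 0.13) passed when adjusted over the list alone, and 0 of the 30 passed over all genes. The set's call ended without saline replicate 3 (0.929), yoked replicate 1 (0.170) or yoked replicate 2 (0.774), and Fos turned to −0.08 without yoked replicate 2. The set's call held with the replicate block (0.000367), without all libraries numbered 1 (0.00171) and with the length trend removed (0.0212). Bdnf was at 0.11 ± 0.24, Colgalt2 at −0.03 ± 0.33, Junb at −0.02 ± 0.36 and Egr1 at −0.01 ± 0.29. Without saline replicate 2 Bdnf turned to −0.03, Junb to 0.27 and Egr1 to 0.20. Colgalt2 turned to 0.18 without saline replicate 1, 0.14 without yoked replicate 2 and 0.08 without yoked replicate 3, Junb to 0.01 and 0.17 and Egr1 to 0.05 and 0.08 without yoked replicates 1 and 3.

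Oxidative phosphorylation genes were below saline in 75 of 80 in the yoked group (median −0.16, adjusted p = 0.00240), ribosomal protein genes in 67 of 78 (−0.15, 0.000795) and proteasome subunits in 35 of 38 (−0.09, 0.0448), with adjusted p = 0.956 with an estimated correlation for each. Rpl15 was at −0.40 ± 0.28 and the complex III gene Uqcrb at −0.35 ± 0.34, the latter 0.04 without saline replicate 1. Within numbers 1, 2 and 3 the oxidative phosphorylation median was −0.17, 0.06 and −0.35. Without saline replicate 1, yoked replicate 2 or yoked replicate 3 the calls ended for oxidative phosphorylation (0.193, 0.265, 0.918), ribosomal protein (0.867, 0.0597, 0.761) and proteasome genes (0.0821, 0.643, 0.542), with the direction turned except for all 3 without yoked replicate 2 and for ribosomal protein genes without yoked replicate 3; the proteasome call also ended without cocaine replicate 3 (0.0621). All 3 were called lower with the replicate block (1.8e-09, 3.8e-06 and 0.000496) and without all libraries numbered 1 (2.3e-10, 3.0e-06 and 0.00257). Ribosomal protein genes were called with the length trend removed (0.0459). Their median went from −0.16 (SD across genes 0.19) to −0.11 (SD 0.18). Oxidative phosphorylation genes were not called (0.0563; −0.17, SD 0.17, before and −0.10, SD 0.17, after). Proteasome genes (0.0504 before, 0.157 after) and sodium and calcium channels (0.0504 before, 0.210 after) were not called on the genes with a known length. With both the block and the trend removal, oxidative phosphorylation (1.8e-05), ribosomal protein (0.0107) and proteasome genes (0.0137) were called lower and the channels were not called (0.130). Nuclear noncoding RNAs were above saline in 8 of 8, without a call (0.28, 0.476; 0.00116 with the replicate block and 8.5e-05 without the libraries numbered 1; adjusted p = 0.999 with an estimated correlation). The block and the trend removal together left them called (0.00406). The number of called lists fell from 9 to 3 without saline replicate 1 or yoked replicate 2 and to 5 without yoked replicate 3. Cholesterol synthesis genes lost their call without saline replicate 2 (0.398), saline replicate 3 (0.157) or yoked replicate 1 (0.755). Haemoglobins lost it without saline replicate 1 (0.537), saline replicate 3 (0.0993), yoked replicate 1 (0.0501), yoked replicate 2 (0.458) or all libraries numbered 1 (0.278). Sodium and calcium channels lost it without any of 7 libraries (0.0631 to 0.743), keeping it without cocaine replicate 1 and yoked replicate 2, and without all libraries numbered 1 (0.253).

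Gene by gene, edgeR called 0 genes between yoked and saline (lowest adjusted p = 1.0), with 66 at an unadjusted p under 0.05, 41 higher and 25 lower. DESeq2 called 0 and had 132, and the blocked fit called 0 (lowest adjusted p = 0.9996) and had 493. The groups did not overlap in 4.29% of genes, where chance gives 10% for independent libraries and the same simulations gave 3.16% to 3.69%. Unblocked, 0 members of each list passed over all genes and 0 adjusted over the list alone, whereas with the block up to 2 of a list passed over the list alone. The genes named by the smallest unadjusted p, none of which pass, were Jam3 (0.47 ± 0.18), Aldh4a1 (0.57 ± 0.22), the aldehyde dehydrogenase gene Aldh9a1 (0.42 ± 0.18), Fbxw4 (0.46 ± 0.21) and the sodium-proton exchanger Slc9a5 (0.43 ± 0.21) among the higher, and Mob3c (−0.51 ± 0.19), the DNA repair gene Rbbp8 (−0.57 ± 0.22), the centriole gene Ofd1 (−0.41 ± 0.17), Qtrtd1 (−0.92 ± 0.38) and Zfp945 (−0.38 ± 0.17) among the lower. Thalamic, endothelial, heat shock, kinase and second messenger, and Y-linked lists, none of them called, had a median, a mean and a test that differed in sign.

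Cocaine against yoked sets self-administration against the yoked control, and is also the test of whether the changes against saline differ between these groups. Sets of excitability genes were called lower after cocaine than in yoked controls with the preset correlation, and 0 sets with an estimated correlation or with fry (lowest adjusted p = 0.148 and 0.153, and 0.551 and 0.269 with the replicate block). Fold changes in this contrast also followed transcript length (Spearman correlation across genes −0.497 with the replicate block). Glutamate receptor genes were below yoked in 22 of 22 (median −0.20, adjusted p = 3.0e-05, and adjusted p = 0.148 with an estimated correlation), with Gria3 at −0.30 ± 0.16 (303.4 ± 17.1 against 372.3 ± 38.1 CPM, SD, n = 3 each) and the NMDA receptor subunit Grin2a at −0.56 ± 0.30. Sodium and calcium channels were below it in 30 of 33 (−0.22, 3.3e-06, and adjusted p = 0.148 with an estimated correlation), with Scn8a at −0.36 ± 0.17 and the calcium channel Cacna1a at −0.35 ± 0.15 (35.3 ± 2.45 against 45.0 ± 4.41 CPM, SD, n = 3 each). Potassium channels were below it in 30 of 36 (−0.19, 2.3e-05, and adjusted p = 0.335 with an estimated correlation), with Kcnh7 at −0.25 ± 0.15. These 3 sets were called whichever library was left out, and without all libraries numbered 1 (0.00246, 0.00765 and 0.00657). With the length trend removed, sodium and calcium (0.0386) and potassium channels (0.00452) were called, but their median differences in log2 CPM shrank from −0.22 (SD across genes 0.17) to −0.09 (SD 0.11) and from −0.23 (SD 0.31) to −0.08 (SD 0.30). Glutamate receptor genes were not (0.0764; 0.0531 with the replicate block as well), as their median difference went from −0.21 (SD 0.16 across genes) to −0.11 (SD 0.15). Within replicate numbers 1, 2 and 3 the glutamate receptor median was −0.29, −0.12 and −0.22. With the replicate block, 3 of 22 glutamate receptor genes passed when adjusted over the list alone and 0 over all genes: Grik3 (−0.61 ± 0.12), Grin2a (−0.58 ± 0.14) and Grin2b (−0.56 ± 0.14), of which Grik3 and Grin2b were chosen after their values were seen.

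Monoamine and acetylcholine receptors were called lower after cocaine than in yoked controls, with 28 of 41 below (−0.16, adjusted p = 0.0155, and adjusted p = 0.335 with an estimated correlation). The nicotinic subunit Chrna4 was at −0.36 ± 0.13 (41.3 ± 1.52 against 53.0 ± 3.02 CPM, SD, n = 3 each) and Chrna7 at −0.66 ± 0.23. Scaffold genes were below in 24 of 29 (−0.15, 0.00110, and adjusted p = 0.345 with an estimated correlation), vesicle genes in 21 of 25 (−0.08, 0.0155, and adjusted p = 0.550 with an estimated correlation) and GABA receptors in 11 of 14 (−0.13, 0.0183, and adjusted p = 0.745 with an estimated correlation). Endothelial markers were below in 11 of 12 (−0.37, 0.00431, and adjusted p = 0.345 with an estimated correlation). Neuropeptides were above in 14 of 17 (0.23, 0.0171, and adjusted p = 0.470 with an estimated correlation), with Cartpt at 0.49 ± 0.22. Without all libraries numbered 1 the calls ended for scaffold (0.327), vesicle (0.369), GABA receptor (0.369), endothelial (0.0771) and neuropeptide genes (0.0639). Without yoked replicate 1 they ended for monoamine and acetylcholine receptors (0.132), scaffold (0.163), vesicle (0.571), GABA receptor (0.852) and endothelial genes (0.252). Without cocaine replicate 1 they ended for scaffold (0.0528) and neuropeptide genes (0.369), without cocaine replicate 2 for monoamine and acetylcholine receptors (0.0698), vesicle (0.0836) and GABA receptor genes (0.107), without cocaine replicate 3 for monoamine and acetylcholine receptors (0.198), GABA receptor (0.349) and endothelial genes (0.119), and without yoked replicate 3 for monoamine and acetylcholine receptors and neuropeptides (0.0717 each). The GABA receptor call ended with the replicate block (0.130). With the length trend removed, monoamine and acetylcholine receptors (0.0137) and endothelial genes (0.00150) were called. The calls ended for scaffold (0.779; median −0.13, SD across genes 0.18, before and 0.02, SD 0.15, after), vesicle (0.206; −0.09, SD 0.21, and −0.05, SD 0.13), GABA receptor (0.729; −0.11, SD 0.16, and −0.005, SD 0.13) and neuropeptide genes (0.779; 0.24, SD 0.18, and 0.05, SD 0.13).

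Oxidative phosphorylation genes were above yoked after cocaine in 79 of 80 (median 0.56, adjusted p = 2.9e-11), ribosomal protein genes in 77 of 78 (0.56, 3.4e-13), proteasome subunits in 37 of 38 (0.43, 6.7e-10) and histones in 23 of 25 (0.49, 0.00166), each with adjusted p = 0.745 with an estimated correlation. Ndufb8 was at 0.90 ± 0.48, Rpl7a at 0.80 ± 0.37 and Psmd13 at 0.61 ± 0.32. The oxidative phosphorylation median within numbers 1, 2 and 3 was 0.86, 0.07 and 0.31. Without cocaine replicate 1 the calls ended for oxidative phosphorylation with the direction turned (0.357), and for ribosomal protein (0.609), proteasome (0.107) and histone genes (0.681). Without all libraries numbered 1 the first 3 were called (3.3e-10, 4.9e-06 and 1.7e-13) and histones were not (0.115). The first 3 were also called with the length trend removed (1.7e-05, 1.6e-06 and 1.6e-06), but smaller. Their medians went from 0.42 (SD across genes 0.15) to 0.21 (SD 0.18), from 0.44 (SD 0.18) to 0.21 (SD 0.19) and from 0.39 (SD 0.17) to 0.24 (SD 0.15). Histones were not called (0.364; 0.38, SD 0.31, before and 0.13, SD 0.35, after). Nuclear noncoding RNAs were below yoked in 8 of 8, without a call (−0.78, 0.214; 9.9e-07 with the replicate block; adjusted p = 0.991 with an estimated correlation), with medians of −0.50, −0.18 and −1.29 within numbers 1, 2 and 3. Removal of the length trend brought their median from −0.85 (SD 0.44) to −0.41 (SD 0.34; 0.420, and 3.1e-05 with the block).

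Immediate early genes were not called between cocaine and yoked, with 13 of 30 above (median −0.03, adjusted p = 0.988). Npas4 was at 0.34 ± 0.39, Junb at 0.33 ± 0.36, Egr1 at 0.12 ± 0.29, Nr4a1 at −0.18 ± 0.24, Arc at −0.15 ± 0.34, Fosb at −0.12 ± 0.28, Fos at −0.05 ± 0.47 and Bdnf at −0.01 ± 0.24, and Colgalt2 at −0.09 ± 0.33. The sign turned without yoked replicate 2 for Nr4a1 (0.05), Arc (0.22) and Fos (0.43), without cocaine replicate 1 for Fosb (0.16) and Fos (0.10), and without cocaine replicate 2 for Npas4 (−0.07), Egr1 (−0.09), Bdnf (0.09) and Colgalt2 (0.01). It also turned without cocaine replicate 3 for Fos (0.01), Bdnf (0.02) and Colgalt2 (0.06), without yoked replicate 1 for Bdnf (0.10) and Colgalt2 (0.25), and without yoked replicate 3 for Bdnf (0.04).

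Gene by gene, edgeR called 0 genes between cocaine and yoked (lowest adjusted p = 0.972), with 182 at an unadjusted p under 0.05, 104 higher and 78 lower. DESeq2 called 0 and had 318, and the blocked fit called 0 (lowest adjusted p = 0.130) and had 3006. The groups did not overlap in 5.62% of genes, where chance gives 10% for independent libraries and the simulations gave 3.17% to 3.72%. Unblocked, 0 members of each list passed over all genes and 0 adjusted over the list alone. With the block 0 passed over all genes, and over the list alone 56 of 80 oxidative phosphorylation genes and 26 of 38 proteasome subunits did, the highest counts of any list. The named higher genes, none of which pass, were Ift27 (0.56 ± 0.16), Nmral1 (0.83 ± 0.25), Zfp277 (0.49 ± 0.16), Ccdc90b (0.54 ± 0.18) and the Mediator subunit Med27 (0.46 ± 0.16; 42.3 ± 5.60 against 30.8 ± 3.70 CPM, SD, n = 3 each). The lower were H6pd, which supplies NADPH in the endoplasmic reticulum (−0.90 ± 0.23), the neurotrophin receptor Ntrk3 (chromosome 7, 78175959 to 78738012) at −0.48 ± 0.14 (38.4 ± 3.13 against 53.5 ± 3.45 CPM, SD, n = 3 each), Lrp1b (−0.48 ± 0.15), the kappa opioid receptor Oprk1 (chromosome 1, 5588466 to 5606131) at −0.49 ± 0.16 (6.84 ± 0.654 against 9.59 ± 0.448 CPM, SD, n = 3 each) and Jade3 (−0.48 ± 0.17). Layer 6, striatal, thalamic, oligodendrocyte precursor, microglia, choroid plexus, haemoglobin and immediate early lists, none of them called, had a median, a mean and a test that differed in sign.

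Across all 3 groups together, the edgeR test called 0 genes (lowest adjusted p = 1.0), with 79 at an unadjusted p under 0.05. DESeq2 called 0 with 186, and the blocked fit called 0 with 2186 (lowest adjusted p = 0.295).

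The changes of cocaine and of yoked against saline share the same 3 saline libraries, which makes them alike without any effect. Across 16417 genes, which are not independent replicates, their log2 fold changes correlated with r = 0.322 (Spearman correlation 0.138), 52.0% had the same sign and 0 calls were shared. In 20 simulations without effects that kept the shared controls and the replicate-number differences, r was 0.474 to 0.515 and 66.0% to 67.3% had the same sign. The genes were simulated independently of each other, so these and the following simulated ranges are too narrow for genes that vary together. They cannot tell whether a measured value lies outside chance. The measured r was −0.24 among the 5000 genes with the highest mean CPM, where the simulations gave 0.486 to 0.520. Having fewer controls than treated libraries raises the value without an effect. Without saline replicates 1, 2 and 3 r was 0.598, 0.608 and 0.495, against simulated values of 0.713 to 0.733, 0.694 to 0.719 and 0.651 to 0.681.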

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

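The tests of RNA close to the input, of a smaller share of glia and of length and GC content over all genes in this part were chosen only after the result was seen, as were the correlation and the list tests after removal of a length trend; the other tests were set before their results were seen.

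Reads given to no single gene are outside the comparisons, and 5 shares lay above the highest saline library. Reads outside annotated genes were 14.7% in yoked IP replicate 2 and 15.5% in yoked IP replicate 3, against at most 14.4% in saline libraries. Reads over several genes were 1.91% in yoked IP replicate 1 and 7.34% in the cocaine unbound library, against at most 1.86%. Reads aligned to several places were 47.0% in cocaine IP replicate 1, against at most 40.6%.

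The libraries numbered 1 stood apart from those numbered 2 and 3 in every IP group, with 7827 genes past the threshold of the replicate-number term. Depth is argued against, since 7703 genes passed with every library thinned to 33633470 gene counts. A smaller share of glia in the dissected tissue is argued against as the whole cause, though it could have a part in the fall of glial markers. Interneuron markers lay under layer 5 markers by −1.43 (log2) in the treatment group nearest to 0. The difference followed transcript length (Spearman correlation across genes −0.409), but length and GC content are argued against as the whole cause, since their trend held 10.3% of its variance, 7562 of 15041 genes passed the limma test for the number after its removal and 7230 before, and the layer 5 median minus the glial median was 2.03 after and 1.93 before. By layer 5 markers alone, RNA in the numbers 2 and 3 close to the unpurified input could account for 5 of the 6 libraries. Their medians over the input were −0.10 to 0.07. By this measure it could not account for saline IP replicate 3 at 0.38 (0.376 before rounding to 2 decimals). Over 10495 genes, however, saline IP replicate 3 correlated with the input at 0.993 (Spearman), within the 0.988 to 0.997 of the 6. The libraries numbered 1 correlated with the input at 0.870 to 0.949. The measures differ for saline IP replicate 3, so this explanation stays open for it. Index sequence and replicate number cannot be told apart, since each number has its own index in every group, and no other biological explanation was tested because no group in the design follows the number.

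Cocaine against yoked had an unadjusted p under 0.05 in 18.3% of genes once the replicate number was a term, though 0 genes passed. Whether the libraries numbered 1 carry this stays open, since a loss of samples alone can lower the share, which was 9.84% without them, 21.3% without the libraries numbered 2 and 8.58% without those numbered 3. A trend with transcript length stays open, with a Spearman correlation across genes of −0.497 between length and the blocked fold change (−0.597, −0.0687 and −0.282 within numbers 1, 2 and 3); with the trend removed, 7 of the 13 lists called before on the same genes were called. A treatment difference present in every number also stays open, since ratios in number 1 correlated across genes with the mean of numbers 2 and 3 at 0.303, and at 0.205 after the length trend was removed; the pairs of numbers gave 0.1001 (1 and 2), 0.309 (1 and 3) and 0.1003 (2 and 3). Cocaine and yoked libraries ran on different lanes, so a lane effect and a treatment effect cannot be told apart.

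Other splits of the libraries bear on the counts. For the test over all 3 groups the real count was 0, which all 100 of the 100 splits drawn reach by construction, so this count says nothing about chance; the highest other split gave 7311. The 4 drawn splits that called any gene all put the libraries numbered 1 together. The grouping by replicate number was among them, with 7235 genes. The others, which mixed numbers 2 and 3, gave 7062, 7074 and 7311. This points to a structure of the samples by number 1 against the rest. The blocked count for the 3 groups was 0. For each contrast of 3 against 3 libraries the 10 splits are too few for a share under 0.05. The real gene count was 0 in each, equalled by all 10 of 10 splits by construction, with a highest other of 0. For called lists, cocaine against saline had 16, reached by 4 of 10 splits with a highest other of 20, yoked against saline had 9, reached by 6 of 10 with a highest other of 17, and cocaine against yoked had 13, reached by 5 of 10 with a highest other of 20. Among the other splits that part all 3 same-number pairs, the highest were 18, 6 and 13.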

How the results depend on the processing

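The runs without the libraries numbered 1, with or without the block, the blocked run without cocaine replicate 1, the run without Rn45s, the list tests with a length trend removed and the enrichments from parts of the replicates were chosen only after the result was seen. Every gene count of the 3 contrasts and of the test over 3 groups was 0 under every alternative run, with edgeR and with DESeq2. Of 2061 values of named genes under an alternative, 2005 kept their direction and stayed short of the threshold and 56 reversed, in 21 of 92 pairs of gene and comparison; 0 passed the threshold. The replicate block changed no call of a gene, though it changed calls of lists. The cause of a change was not tested, except where fewer libraries had to pass or were left to test.

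The list tests depended on the correlation. With an estimated correlation, and with fry, 0 lists were called for cocaine against saline, 0 for yoked against saline and 0 for cocaine against yoked. With the replicate block, 24 were called for cocaine against saline in place of 16, 15 for yoked against saline in place of 9 and 15 for cocaine against yoked in place of 13; with the block, too, 0 were called in each contrast with an estimated correlation (lowest adjusted p = 0.340, 0.747 and 0.551) and 0 with fry. With the length trend removed, 8, 5 and 7 were called in this order (17, 6 and 13 on the same genes before), and with the replicate block as well 13, 12 and 8 (22, 14 and 14 before). In these runs 0 were called with an estimated correlation and 0 with fry, with and without the block. Leaving out 1 library gave 12 to 21, 3 to 13 and 11 to 15.

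For saline IP over input, genes higher and lower in all libraries were 5 and 2 with a prior count of 10, 395 and 1397 with only the library numbered 1, 16 and 10 with only numbers 2 and 3, and 0 and 0 by edgeR over all 11 libraries; leaving out 1 library gave 16 to 27 higher and 10 to 41 lower. For cocaine IP over unbound they were 2588 and 1938 with only number 1, 168 and 459 with only numbers 2 and 3, and 3 and 17 by edgeR; leaving out 1 library gave 123 to 239 higher and 305 to 459 lower. The correlation of changes against saline was −0.24 over the 5000 genes with the highest mean CPM, 0.45 without the libraries numbered 1, and 0.495 to 0.608 when 1 saline library was left out. For these, simulations without effects gave 0.486 to 0.520, 0.473 to 0.513 and 0.651 to 0.733. Their genes were drawn independently, so these ranges are too narrow for genes that vary together.

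Apart from Ndufb8 and Uqcrb, each gene with a reversal had a log2 fold change in the main result smaller than its standard error; the cause was not tested. For yoked against saline, Egr1 was at 3.0e-04 with RLE factors, 0.0042 with upper-quartile factors, 0.0039 with the block, 0.0049 with the block and without cocaine replicate 1, and 3.0e-04 with DESeq2; Colgalt2 was at 0.15 with the glial and vascular term and 0.036 over genes above 0 in IP over input; Junb was at 0.013 with the block and without the libraries numbered 1. For cocaine against saline, Egr1 was at −0.012 with the glial and vascular term. For cocaine against yoked, Fos was at 0.084 with the block, 0.026 with the glial and vascular term, 0.061 without the libraries numbered 1, 0.27 with the block and without them, and 0.28 with the block and without cocaine replicate 1; Fosb was at 0.087, 0.084 and 0.082 in the last 3 of these runs. Leaving out 1 library, which also leaves the replicate numbers unequal between groups, gave these ranges. For cocaine against saline they were −0.18 to 0.40 for Fosb, −0.070 to 0.32 for Bdnf, −0.10 to 0.35 for Egr1, −0.44 to 0.086 for Colgalt2, −0.48 to 0.25 for Npas4, −0.13 to 1.04 for Ndufb8 and −0.91 to 0.044 for Pou3f1. For yoked against saline they were −0.085 to 0.78 for Fos, −0.026 to 0.33 for Bdnf, −0.37 to 0.18 for Colgalt2, −0.29 to 0.27 for Junb, −0.17 to 0.20 for Egr1 and −0.56 to 0.043 for Uqcrb. For cocaine against yoked they were −0.070 to 0.57 for Npas4, −0.34 to 0.054 for Nr4a1, −0.39 to 0.22 for Arc, −0.42 to 0.16 for Fosb, −0.091 to 0.35 for Egr1, −0.42 to 0.25 for Colgalt2, −0.38 to 0.43 for Fos and −0.18 to 0.10 for Bdnf. Depth limits the unbound library most, with 20926712 gene counts against 33633470 or more elsewhere, and genes of a few CPM, whose ratios move with the prior count.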

Other observations

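No test in this part was planned as an explanation, and the values below were chosen only after they were seen.

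Some gene groups moved once the replicate number was accounted for, without a call in the main test. Inhibitory interneuron markers were above saline after cocaine in 11 of 16 (median log2 0.24, adjusted p = 0.0618; 0.00617 with the replicate block and 0.00234 without the libraries numbered 1; adjusted p = 0.650 with an estimated correlation), with medians of 0.16, 0.04 and 0.38 within numbers 1, 2 and 3. Heat shock genes, which encode chaperones, were above yoked after cocaine in 7 of 10 (0.16, 0.214; 0.0424 with the block and 0.00246 without the libraries numbered 1; adjusted p = 0.991 with an estimated correlation). Chromatin regulators were below saline after cocaine in 22 of 33 (−0.12, 0.117; 0.00145 with the block; adjusted p = 0.650 with an estimated correlation), with medians of −0.33, −0.08 and 0.01 within numbers 1, 2 and 3. With the block and a length trend removed, interneuron markers were called (0.00208) and chromatin regulators were not (0.606), nor were heat shock genes against yoked (0.102). Circadian clock genes and glucocorticoid-induced genes were not called in any contrast; their lowest adjusted p was 0.109, for glucocorticoid-induced genes after cocaine against saline (median 0.08, 11 of 15 above).

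Markers of striatal projection neurons bear on the tissue, for which the labels name cortex and the extraction text names whole striatum. Ppp1r1b, a phosphatase inhibitor abundant in striatal neurons, was at 86.9 to 163.1 CPM in the 11 libraries, and the dopamine receptor Drd2 at 2.45 to 10.1 CPM. The cortical vesicular glutamate transporter Slc17a7 was at 262.8 to 459.8 CPM and the cortical transcription factor Neurod6 at 121.6 to 168.5 CPM. No tissue of known origin was measured beside them.

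The unbound library differed from every other library, the input included. AK140265 was at 80437 CPM in it, at 1651 CPM in the input and at 111.9 to 500.6 CPM in the IP libraries. Kalrn was at 439.6 CPM in it, 5034 CPM in the input and 3740 to 7618 CPM in the IP libraries. The input over unbound log2 ratio was 3.52 for Kalrn and 2.43 for Atg7. Rpl10a, the ribosomal protein gene whose tagged copy defines the line, was at 1.18 to 3.67 CPM across the 11 libraries. Ttr was at 20.97 CPM in saline IP replicate 2, at 30.0 CPM in the unbound library and at most at 1.34 CPM elsewhere.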
